A study of Arabidopsis thaliana with 4 samples.

How the data were processed

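Steady-state RNA levels were measured in detached source leaves of Arabidopsis thaliana, ecotype Col-0, on Affymetrix ATH1 arrays, which carry 1 biotin-labelled sample each. The 4 arrays fell into 2 groups of 2 by their titles, leaves fed 100 mM sorbitol and leaves fed 100 mM sucrose. Per the labels' protocols, total RNA was extracted with TRIzol and 10 µg was labelled. The labels do not say whether the replicates came from separate plants or harvests, so p-values measure only the spread between these arrays, which may be technical.

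The deposited table held 1 intensity per probe set and array for 22810 probe sets. Per the submitters' processing notes, the authors made these intensities with MAS5, whose version and settings were not given in the sources used here. From the values, each array's 2 percent trimmed mean was 100.0, so the deposited intensities were taken as linear and scaled per array, and they were not normalised again. The median intensity was 35.6 on sorbitol 1, 30.6 on sorbitol 2, 35.1 on sucrose 1 and 33.8 on sucrose 2. Detection calls and scanner files were not used here, so the number of arrays and the dim end of the scale limit the precision.

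The 64 Affymetrix control probe sets were kept out of all tests. Intensities were converted to log2 after a floor of 0.1, which touched 93 zero values among the 22746 other probe sets and none among those tested. The 13648 probe sets whose mean log2 value lay at or above the 40th percentile (an intensity of 18.6) were tested. Sucrose and sorbitol were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend in mean value), with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. Log2 changes are sucrose minus sorbitol, and errors of levels are SD with n = 2.

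Gene names came from the platform annotation, which gave a single gene for 13513 probe sets, several genes for 503 and none listed for 8730. Of the single-gene probe sets, 13436 matched a gene of the TAIR10.1 name table by gene number and took its current symbol. That table served for names alone, and positions are not given because the array's build was not stated. Of the 580 entries of the gene lists, 99 had a single-gene probe set in this annotation and 90 were bright enough to be tested. Of the 14 genes named in advance, 12 had no single-gene probe set, ASN1, CHS and STP1 among them, and were not analysed here.

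Lists of genes, 31 in all, were fixed by locus before the data were examined, as were the design, the rule for named genes and the first set of alternatives. Each gene was represented by its brightest single-gene probe set. SPP2 and ICDH were left out because their symbols pointed to other loci. The 14 lists with at least 3 measured members were tested with camera, with a preset inter-gene correlation of 0.01 and adjustment over the lists, and the remainder are described without a test. The genes named are the 10 largest rises and the 10 largest falls among genes past the threshold whose sucrose values both lay on 1 side of both sorbitol values, up to 4 members of each list by smallest p, and the genes named in advance.

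Alternatives were no filter, a 60th percentile filter, a pseudocount of 5.3 (the 20th percentile of all values), quantile normalisation, median centring, eBayes without the trend, the replicate number as a block, each array left out in turn, an estimated inter-gene correlation and a mean over the probe sets of a gene. Chosen after seeing the data were a count of 2-fold changes in both pairs and a fit with values below 9.3, the highest intensity of 27 Bacillus control probe sets, raised to it. In the fits without an array, the lone array of a group was assumed to vary like the other group. Arrays were checked for batches through the control probe sets, and changes are given within each replicate number (pair 1 and pair 2) because those controls split the arrays by that number.

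The fit was tested on simulated data with 13648 probe sets, of which 200 were changed. Without a batch effect it recovered 0% of changes of 1 log2 unit, 10% of changes of 2 units, 74% of changes of 3 units and 88% of changes of 4 units, with 2 false calls. The blocked fit then recovered 64% of changes of 3 units, with 6 false calls. With a batch effect as large as the measured difference between replicate numbers, the unblocked fit recovered 54% of changes of 3 units with 0 false calls, and the blocked fit 96% with 9 false calls. That measured difference includes noise between arrays, so the simulated batch may be too large. The simulation therefore favours the block and does not show that these arrays need 1. Camera recovered 100% of lists of 8 genes shifted by -1.5 log2 units and called 5% of unshifted lists at an unadjusted p under 0.05, in a simulation of independent genes. Genes matched on brightness were the 20 nearest in mean log2 value to each of 11 photosynthesis genes, with the interval of their median from 10000 bootstrap draws. Figures were drawn with matplotlib 3.10.9.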

Results

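Full-grown source leaves, the mature leaves that export sugar, were cut from non-flowering plants at the end of a 14 h day. Their petioles stood for 13 h in darkness in 2 mM MES buffer with either 100 mM sucrose or 100 mM sorbitol. Sorbitol served as the control at equal concentration, so the comparison asks how leaf transcript levels differ with sucrose supplied through the petiole. The night of the growth cycle was 10 h, shorter than this darkness, and no array came from leaves before the incubation. A rise or fall below is therefore relative to sorbitol-fed leaves, whose own levels may have changed during the incubation. Each group had 2 arrays, with deposited intensities for 22746 probe sets besides controls, and 13648 of these were bright enough to be tested.

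In sucrose-fed leaves all 5 measured genes of anthocyanin synthesis and all 3 of starch synthesis were higher, of which 4 and 1 passed the test over all probe sets. All 8 measured genes of the light reactions, all 3 of the Calvin cycle and 7 of 8 of chlorophyll synthesis were lower, of which 1 in each list passed. The lists held 26, 18, 44, 21 and 22 genes, in that order. Most of their genes had no single-gene probe set in the annotation, so the measured ones do not stand for the whole pathways. These lists passed as groups with a preset correlation and none did with an estimated one (adjusted p = 0.517 for the light reactions, adjusted p = 0.475 for each of the others). Dihydroflavonol reductase DFR, an enzyme of anthocyanin synthesis, rose from a log2 intensity of 6.90 ± 0.90 (SD, n = 2) in sorbitol to 10.11 ± 0.33 in sucrose, which is 9.27-fold. APL3, a large subunit of the ADP-glucose pyrophosphorylase that makes the precursor of starch, rose 6.67-fold, from 7.74 ± 0.46 to 10.48 ± 0.31. Phosphoribulokinase PRK of the Calvin cycle fell by 2.28 on the log2 scale, from 11.56 ± 0.14 to 9.28 ± 0.53. AKINBETA1, a regulatory subunit of the SnRK1 kinase that acts in energy shortage, fell by 3.40, from 8.11 ± 0.55 to 4.71 ± 0.24.

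In the limma fit 50 probe sets were higher and 126 lower in sucrose at an adjusted p under 0.05, each by at least 2-fold. Of those higher, 22 had a single annotated gene, and of those lower, 58. Within the replicate numbers, 630 probe sets were at least 2-fold higher in both pairs and 753 at least 2-fold lower in both, against 24 that moved at least 2-fold in opposite directions. With the replicate number as a block, 1130 probe sets were higher and 1206 lower, and all 176 called without the block were among them. The block added 22 of the genes named here to those past the threshold and removed 0, and its limma adjusted p is given below as the blocked p. That the replicate number marks a shared batch is not stated in the labels, and the blocked fit leaves 1 residual degree of freedom. A blocked p therefore rests on how alike the changes in pair 1 and pair 2 were, and on the variance shared over probe sets. The counts varied widely in fits without 1 array, which take the spread from the group that keeps 2 arrays. Such counts follow that spread, so they do not show whether the changes themselves rest on 1 array. With no filter on dim probe sets, 1 probe set was higher and 2 lower at a limma adjusted p under 0.05.

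**Figure D1:**
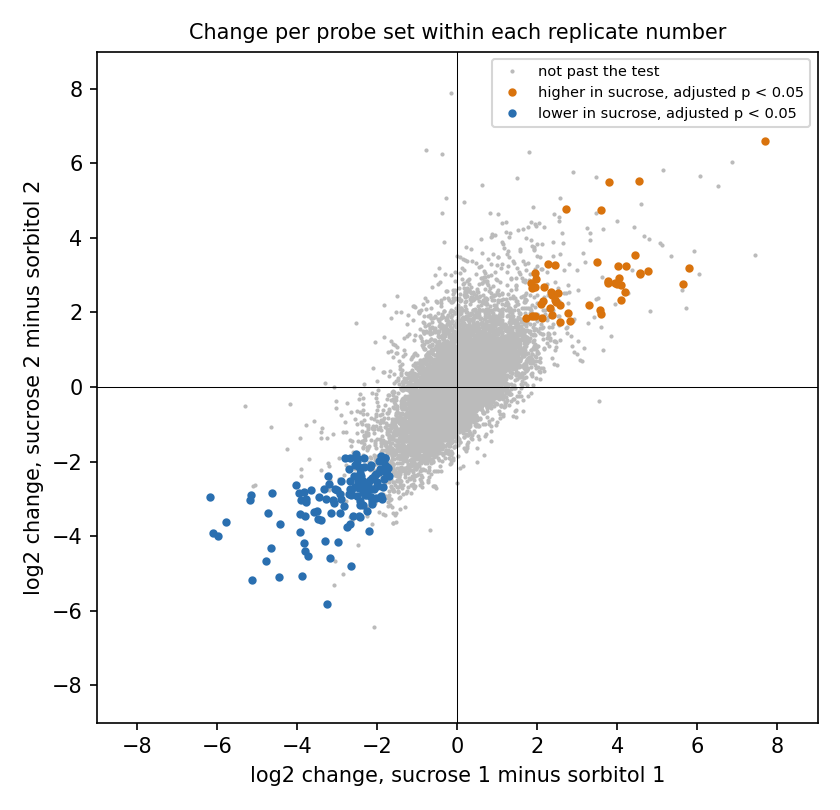
Log2 change of each of the 13648 tested probe sets between sucrose and sorbitol in replicate 1 (horizontal axis) and in replicate 2 (vertical axis). Orange points are the 50 probe sets higher in sucrose and blue points the 126 lower; each called probe set changed in the same direction in both replicate numbers.

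GSTU25, a tau-class glutathione S-transferase, rose with a log2 change of 5.02 ± 0.67 SE (limma adjusted p = 0.0372) and levels of 2.41 ± 0.63 in sorbitol and 7.43 ± 1.32 in sucrose. Its sorbitol values lay below the highest intensity of 27 Bacillus control probe sets, 9.3, a level at which the size of a change, and its rank among the rises, is uncertain. With values below 9.3 raised to it, a setting chosen after seeing the data, GSTU25 rose by 4.21. AT1G26380 and AT1G26390, both of the berberine bridge enzyme-like family, rose by 4.18 and 3.74 on the log2 scale, and by 4.099 and 3.54 with dim values raised. The remaining genes among the 10 largest rises outside the anthocyanin list were AT1G61930 with 3.73, AT2G16890 with 3.49 (3.22 with dim values raised), AT4G34950 with 3.37 and AT4G37295 with 3.36. Each was higher on both sucrose arrays than on both sorbitol arrays, which the rule for naming these genes required.

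The largest fall was that of AT2G29290, a short-chain dehydrogenase of the tropinone reductase-like family, which fell by 5.15 ± 0.29 SE (limma adjusted p = 0.00923). Its changes in pair 1 and pair 2 were -5.14 and -5.16. AT5G18600, a glutaredoxin, fell by 5.01, from 9.93 ± 0.61 to 4.92 ± 0.93. AT4G27450 fell by 4.57, AT5G59080 fell by 4.49, AT3G22210 fell by 4.14 and AT1G49200 fell by 4.05. AT4G33666 fell by 3.74, AT1G22630 fell by 3.73, AT5G02160 fell by 3.63 and AT5G39080 fell by 3.47. At least 1 sucrose value of 4 of these genes lay at or below the control level, and with dim values raised AT4G27450 fell by 4.44, AT5G59080 fell by 4.46, AT1G49200 fell by 3.41 and AT5G39080 fell by 3.23. Their sizes, and the order among the largest changes, are uncertain to that extent. Of these 10 genes, AT4G27450 differed most between pairs, with -6.18 in pair 1 and -2.96 in pair 2.

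All 5 measured members of the anthocyanin and flavonoid list were higher in sucrose, with a median log2 change of 3.79 (4.45 in pair 1, 2.78 in pair 2), and 4 of them rose. All 5 passed when adjusted over the list alone. The list rose as a group (camera adjusted p = 2.23e-07), a call lost at adjusted p = 0.475 with an estimated correlation. CHIL, a chalcone isomerase-like protein, rose by 4.21, from 3.76 ± 1.07 to 7.97 ± 0.96, with 1 sorbitol value below the control level, and by 4.101 with dim values raised. The anthocyanin glycosyltransferases UGT75C1 (AT4G14090) and UF3GT (AT5G54060) rose 15.9-fold and 13.9-fold. UGT78D2, a flavonoid glucosyltransferase and the remaining member, named after its values were seen, had a log2 change of 2.33 and did not pass over all probe sets.

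The starch synthesis list had 3 measured members, all higher in sucrose, with a median of 2.74 (3.28 in pair 1, 2.19 in pair 2). It rose as a group (camera adjusted p = 0.000228), which was lost at adjusted p = 0.475 with an estimated correlation. APL3 rose, whereas APL4, a further large subunit, had a log2 change of 4.23 at adjusted p = 0.0576 and the branching enzyme SBE2.2 a change of 1.82 at adjusted p = 0.0645, both from limma. With the block both passed, at a blocked p of 4.63e-06 for APL4, which had 1 sorbitol value below the control level, and of 0.00272 for SBE2.2. Adjusted over the list alone, all 3 passed. For starch breakdown, DPE1 had a change of 0.95 and PWD of -0.34, and neither passed, with or without the block.

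All 8 measured members of the light reaction list were lower in sucrose, with a median of -1.03 (-0.78 in pair 1, -1.31 in pair 2). In the unblocked fit of all 4 arrays only PSAN, a subunit of photosystem I, passed over all probe sets, falling by 2.26 (limma adjusted p = 0.0497), and 6 passed adjusted over the list alone. LHCB4.1, PSBY and PSBW had changes of -1.01, -1.23 and -0.94, and passed with the block at a blocked p of 0.0197, 0.0131 and 0.0350. All 3 Calvin cycle genes were lower, with a median of -1.75 (-1.32 in pair 1, -2.18 in pair 2): PRK fell, and SBPASE and the rubisco activase RCA had changes of -1.75 and -1.61, with a blocked p of 0.00266 and 0.00241. All 3 passed adjusted over the list alone. Both lists fell as groups (camera adjusted p = 0.000169 for light reactions and 0.00115 for the Calvin cycle), and with an estimated correlation both calls were lost, at adjusted p = 0.517 and adjusted p = 0.475.

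Of 8 chlorophyll synthesis genes 7 were lower in sucrose, with a median of -1.15 (-0.94 in pair 1, -1.25 in pair 2). PORB, a protochlorophyllide oxidoreductase, fell by 2.29, and 4 members fell when adjusted over the list alone. CHLM had a change of -2.58 at limma adjusted p = 0.0696, CHLP of -1.42 and HEME1 of -1.06, while GSA1, named after its values were seen, lay in the opposite direction at 0.83. With the block CHLM, CHLP and HEME1 passed, at a blocked p of 0.000275, 0.00424 and 0.0296. The list fell as a group (camera adjusted p = 0.00431), lost at adjusted p = 0.475 with an estimated correlation. RNA quality moved with these groups on 1 array: the 3 prime minus 5 prime difference of the older GAPDH control was 0.20 log2 units on sucrose 2, against 1.85 on sorbitol 1, 1.44 on sorbitol 2 and 1.43 on sucrose 1.

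**Figure D2:**
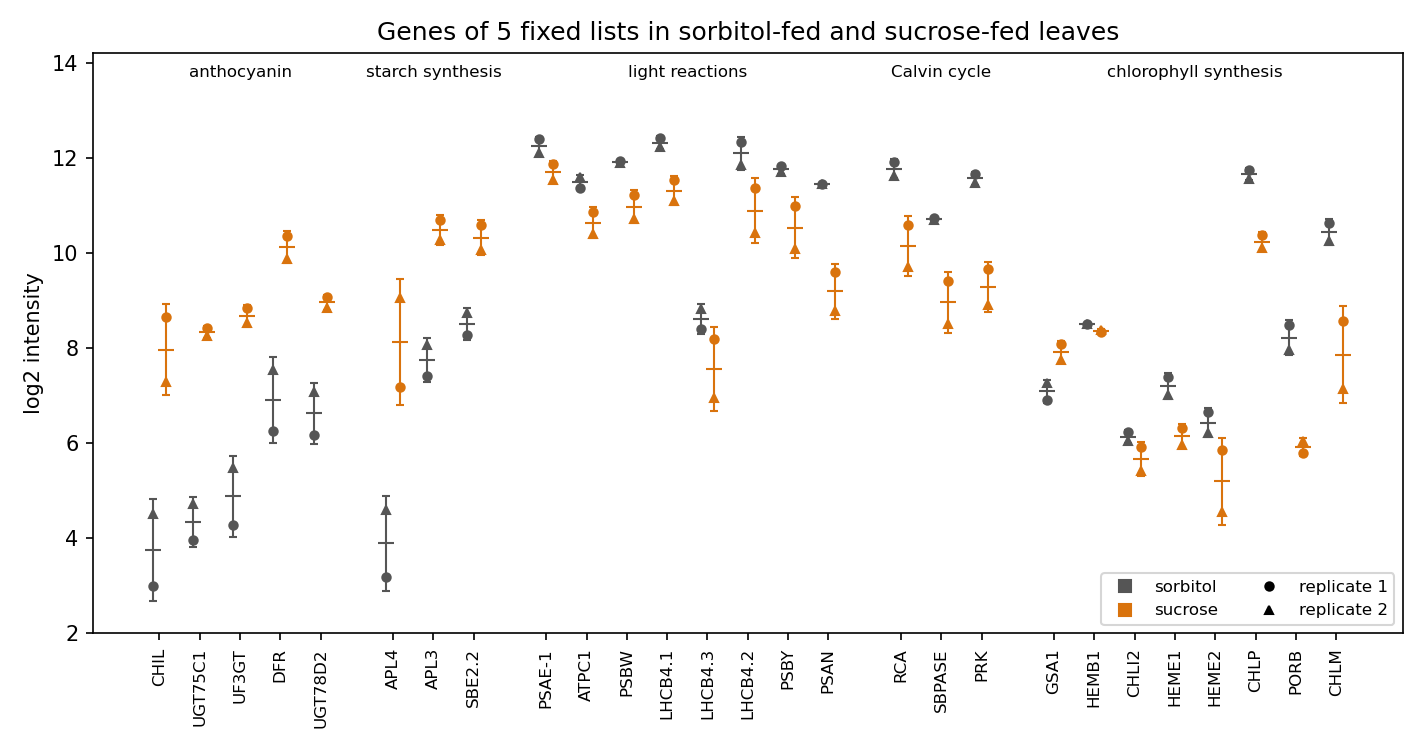
Log2 intensity of each measured gene of 5 lists in sorbitol (grey) and sucrose (orange). Circles are replicate 1, triangles replicate 2, and bars the mean and SD of 2 arrays. DFR stood at 6.90 in sorbitol and 10.11 in sucrose, and PRK at 11.56 and 9.28.

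The oxidative pentose phosphate list had 3 measured members with a median of 0.45 (0.42 in pair 1, 0.51 in pair 2). PGD3, a 6-phosphogluconate dehydrogenase, rose 4.76-fold, while PGD1 and PGD2 had changes of 0.45 and 0.41. The list passed narrowly (camera adjusted p = 0.0484) and did not pass with the replicate number as a block (adjusted p = 0.0612), nor with an estimated correlation (adjusted p = 0.475). The call was also lost with the 60th percentile filter (adjusted p = 0.0579) or no trend (adjusted p = 0.0555), both from camera. It was lost too without sucrose 1, without sorbitol 2 and without sucrose 2, although the median was larger there, at 0.65, 0.56 and 0.74.

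The remaining 8 tested lists did not pass with camera. Among 9 sugar transporters, 5 were higher and 4 lower, with SWEET11, a sucrose exporter, at -1.89 (limma adjusted p = 0.0625), TMT2 at 1.14 and STP3 at 0.98, and these 3 passed with the block at a blocked p of 0.00143, 0.0234 and 0.0485. Of 9 amino acid catabolism genes 6 were lower, with a median of -0.43, and MCCA and HML1 had changes of -0.86 and -0.70. Of 11 autophagy genes 8 were lower, with a median of -0.26, and ATG8F had a change of -1.25 (blocked p 0.0107). ATG8E had a change of -1.70 (blocked p 0.0285), with -3.03 in pair 1 and -0.38 in pair 2. The medians were -0.04 for 4 glycolysis genes, 0.79 for 4 expansin and xyloglucan endotransglucosylase genes, 0.14 for 4 abscisic acid and osmotic stress markers, 0.17 for 4 senescence genes and 0.28 for 3 glucosinolate genes. In these lists XTH32 had a change of 1.08 and the senescence-linked WRKY6 of 1.69, with a blocked p of 0.0365 and 0.0121, and neither passed in the unblocked fit of all 4 arrays. Without sucrose 1 WRKY6 passed in limma at an adjusted p of 0.0308. Leaving out 1 array changed 3 of these lists in camera. Autophagy passed without sorbitol 1 (median -0.41) or sucrose 2 (median -0.39), and amino acid catabolism without sorbitol 1 (median -0.58). The abscisic acid list also passed, in opposite directions, at a median of 1.28 without sucrose 1 and of -1.24 without sucrose 2. All 4 of its genes were higher on the replicate 2 array than on the replicate 1 array in both groups. COR15A, for example, had 9.34 and 11.47 on sorbitol 1 and 2, and 9.99 and 11.71 on sucrose 1 and 2. GAPC2, a cytosolic glyceraldehyde-3-phosphate dehydrogenase, had a change of -0.13, which turned to 0.28 with quantile normalisation.

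Lists with fewer than 3 measured members had no test. In the low-oxygen list LDH1 had a change of 2.61 and PDC2 of 1.36. ATSPS4F, a sucrose phosphate synthase, had a change of -1.86 and the invertase BFRUCT3 of -0.29. PES, of ribosome biogenesis, had 1.31, FATB -0.44, AIM1 -0.02, PDF1.2 -1.05 and the guard cell gene FMA -0.33, and none of these genes passed in the unblocked fit of all 4 arrays. With the block LDH1, PDC2, ATSPS4F, PES and PDF1.2 passed, at a blocked p of 0.00108, 0.0159, 0.00451, 0.0136 and 0.0388. AKINBETA1 was the single measured member of the sugar-starvation list. No member was measured for phloem, epidermis and xylem markers, nor for the trehalose phosphate, nitrate, jasmonate, phosphate starvation and clock lists, and these lists were not analysed here.

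The control probe sets separated the arrays by replicate number. The 25S ribosomal RNA control had intensities of 2163 and 1255 on sorbitol 1 and sucrose 1, against 14.4 and 56.6 on sorbitol 2 and sucrose 2. The 5S control had 387.9 and 264.6 against 8.4 and 6.5. Plastid-encoded genes, a group picked after its values were seen, followed the same split, with a median log2 intensity of 10.42 on sorbitol 1 and 9.74 on sucrose 1, against 8.58 and 8.96 on the replicate 2 arrays.

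**Figure D3:**
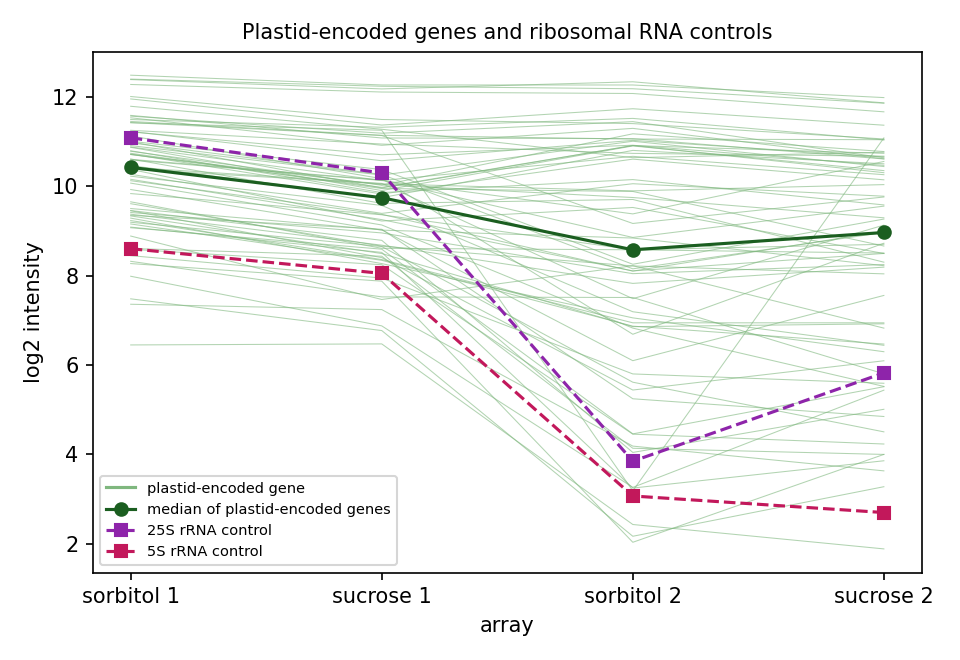
Log2 intensity on each of the 4 arrays of 69 plastid-encoded genes (thin green lines), of their median (dark green circles) and of the 25S and 5S ribosomal RNA control probe sets (squares). The median was 10.42 on sorbitol 1 and 8.58 on sorbitol 2; the lines join arrays for reading and imply no order.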

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

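All tests in this part were chosen after the result was seen. A pair of control probe sets outside the comparison were at least 2-fold higher in sucrose in both pairs. The newer GAPDH control had a log2 difference of 1.201 at its 3 prime probe set and of 1.319 at its 5 prime probe set, and both sucrose arrays lay above both sorbitol arrays. Other controls, these among them, were higher in both pairs without reaching 2-fold in each: the newer actin control by 1.75 at its 5 prime, 0.96 at its middle and 0.83 at its 3 prime probe set, the older actin control by 1.08 at its middle one, and the older GAPDH control by 1.31 at its 5 prime, 1.21 at its middle and 0.48 at its 3 prime one. The genes behind these probe sets are not named here, and GAPC2, which has its own probe set, had a change of -0.13. In the deposited values the spiked controls were not higher in sucrose, the larger of the pair medians of 9 spiked control probe sets being -0.16. Each array had been scaled to the same trimmed mean, so brightness before scaling cannot be tested with these values. A difference in RNA integrity was tested through the 3 prime probe sets. That of the newer GAPDH control was higher by 1.14 in pair 1 and 1.27 in pair 2. It had been picked for a rise of at least 2-fold in both pairs, so this test could not come out otherwise and decides nothing. The 3 prime minus 5 prime difference of this control was 0.044 in sorbitol and 0.15 in sucrose in pair 1. In pair 2 the difference was 0.33 and -0.0074. For the older GAPDH control a difference in RNA integrity stays open too, since its 3 prime probe set was higher by 0.40 and 0.56. A response to sucrose is a hypothesis, which these tests do not separate from other differences between the arrays.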

How the results depend on the processing

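The number of list calls varied less than the counts of probe sets and of named genes, except with an estimated correlation. The 6 list calls numbered 5 to 8 under the filters, scalings, variance model, block and left-out arrays, and 0 with an estimated correlation, which is drawn from few residual degrees of freedom. Calls higher and lower in sucrose (50 and 126) were 1 and 2 with no filter, 83 and 182 with the 60th percentile filter, 25 and 79 with quantile normalisation, and 26 and 77 without the trend, and the 2-fold counts were equal to these. The list test with a mean over probe sets gave 6 calls. Named genes past the threshold (27) were 1 with no filter and 16 with quantile normalisation. The labels do not say that the replicate number marks a shared batch; deviations of same-numbered arrays correlated at 0.43 over probe sets, and 2 pairs do not settle the pairing. With the replicate block the counts were 1130 and 1206 (1079 and 1148 at least 2-fold) and 49 named genes passed; the replicate number itself called 225 and 170 probe sets. Leaving out 1 array gave 0 to 403 higher and 0 to 545 lower, at 2-fold also, and 0 to 37 named genes, and of the 176 calls 0 were kept without sorbitol 1 or sorbitol 2, 176 without sucrose 1 and 77 without sucrose 2. Without sucrose 1, 10 further named genes passed in limma, at an adjusted p of 0.0128 to 0.0486 (SBPASE, RCA, CHLM, CHLP, PSBY, LDH1, WRKY6, APL4, ATSPS4F and SWEET11), without sucrose 2 ATG8E passed at 0.0391, and with the 60th percentile filter APL4 at 0.0437. In the fits without an array the spread came from the group that kept 2 arrays, and their counts follow that spread. A count of 2-fold changes in both pairs, chosen after seeing the data, gave 630 and 753. The median turned to -0.017 for senescence genes with the 60th percentile filter and to 0.21 for glycolysis with quantile normalisation, where GAPC2 turned to 0.28. Leaving out 1 array at a time turned the sign of 3 list medians, which ranged from -0.49 to 0.68 for sugar transporters, from -1.24 to 1.28 for abscisic acid and osmotic stress markers and from -0.17 to 0.085 for glycolysis. Log2 changes of genes that turned ranged from -0.88 to 2.58 for LTI30, -0.62 to 1.505 for COR15A, -1.64 to 0.85 for COR15B, -1.59 to 1.27 for COR47, -0.83 to 0.52 for BCAT4, -0.28 to 0.38 for PPDK, -0.18 to 0.14 for AIM1, -0.094 to 0.059 for WRKY53 and -1.35 to 0.76 for BFRUCT3. None of these had passed with all 4 arrays, and the cause was not tested. Detection calls were not used here; of the 13648 probe sets tested 192 had a value at or below the highest Bacillus control, 18 of the 176 calls among them, and with values raised to that level, a setting chosen after seeing the data, 66 and 147 were called, all 176 included. The cause of the low counts with no filter (22746 tested) was not tested.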

Other observations

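All groups in this paragraph were chosen after their values were seen, 6 were tested with camera and adjusted together, and each call was lost at adjusted p = 0.712 with an estimated correlation. Nuclear-encoded subunits of the chloroplast NADH dehydrogenase-like complex, which carries electrons around photosystem I, were taken by symbol, so subunits under other symbols are outside the group. The 3 measured ones were all lower in sucrose: NdhN had a log2 change of -2.50, NdhL of -2.46 and NdhS of -1.48 (group median -2.46, camera adjusted p = 0.00271). Their group medians were -1.53 in pair 1 and -3.38 in pair 2, the pair that holds sucrose 2. None passed alone. Plastid-encoded genes had a median of -0.35, with 53 of 69 lower (camera adjusted p = 0.00817), and values of -0.65 in pair 1 and -0.28 in pair 2. Among them psaA had log2 intensities of 11.42, 11.25 and 11.08 on sorbitol 1, sucrose 1 and sucrose 2, and of 3.19 on sorbitol 2. Genes named nad, ccb or cox, taken as mitochondrion-encoded, were all 10 higher, with a median of 0.72 (camera adjusted p = 0.0351), but the pair medians differed in sign, -0.17 in pair 1 and 1.37 in pair 2. Taken by symbol alone, genes named UGT (28 genes, median 0.29), GSTU or GSTF (8 genes, median -0.23) and CPN60 (3 genes, median 1.54, with 1 of them lower) did not pass as groups, and glycosyltransferases under other symbols, UF3GT among them, were outside the first. Among the glutathione S-transferases GSTU18 fell by 2.38 while GSTU25 rose by 5.02.

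The lower level of nuclear photosynthesis genes in sucrose was tested against 3 technical or tissue explanations, of which the test of brightness was written before its result and the others after, as was the use of an interval in the brightness test. The 11 light reaction and Calvin cycle genes had a median of -1.20, against -0.18 for 105 genes matched on brightness (bootstrap 95% interval -0.43 to -0.10). That interval reaches past the bound of -0.2 set in advance but excludes -0.60, which is 0.5 times the photosynthesis median, and this argues against a loss of all bright signals as the whole cause. The array with the lower 3 prime to 5 prime difference, sucrose 2, as the sole source is argued against by the median of -0.89 in pair 1, with an upper quartile of -0.62. A smaller share of chloroplast-bearing tissue stays open beside a response to sucrose, since the plastid-encoded median of -0.65 in pair 1 lay below that quartile, although in pair 2 it was -0.28 against -1.62 for the nuclear genes.

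Plastid-encoded genes had a median difference of -1.02 log2 units between the replicate 2 and replicate 1 arrays, with 61 of 69 lower and 23 lower by over 2 units (quartiles -2.50 and -0.27), and the tests of brightness, labelling and the ribosomal RNA controls were chosen after this was seen. In the deposited values 7199 nuclear genes had a median of -0.11, so the plastid-encoded difference was not a shift of the whole scaled range. Each array had been scaled to the same trimmed mean, so this median cannot test brightness before scaling. All older spiked control probe sets but BioDn 5 prime (0.62) were lower on the replicate 2 arrays, down to -1.11 at BioC 5 prime. Weaker labelling of RNA without a poly(A) tail, which plastid and ribosomal RNA largely lack, is a candidate explanation that stays open. The bound against it was a mitochondrial median at or above 0, and 10 mitochondrial genes met it with 0.18. Their quartiles of -0.73 and 0.26, taken into account only after they were seen, lay on both sides of that bound. The groups also moved in opposite directions, with median log2 intensities of 5.21 on sorbitol 1 and 4.79 on sorbitol 2, against 5.15 on sucrose 1 and 6.68 on sucrose 2. Fewer chloroplasts or less photosynthetic tissue in the replicate 2 leaves is argued against for the 25S control, a cytosolic RNA. Its differences were -7.23 and -4.47 in the 2 groups. These differences had themselves defined the split, so the argument rests on where that RNA lies and not on a separate test. For the 5S control, whose compartment is not given here, this explanation stays open. For plastid-encoded genes it stays open: in a test written before its result nuclear photosynthesis genes had a median of -0.41 (quartiles -0.50 and -0.31), nearer 0 than the plastid-encoded median but between the bounds of -0.5 and -0.2 set in advance, and by group -0.12 in sorbitol and -0.83 in sucrose, against -1.21 and -0.66 for plastid-encoded genes.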
